A study of Mus musculus with 2 samples.

How the data were processed

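RNA-seq was done on 2 samples of sorted mouse bone marrow plasma cells, 1 sorted for CD138 and 1 for Blimp1. Per the labels' protocols, total RNA was taken up on magnetic beads, treated with DNase to remove genomic DNA and made into strand-specific mRNA libraries with a KAPA kit. The authors deposited whole-number read counts per gene, by Entrez gene identifier, for both samples in a single table, with no normalization. The genome build was GRCm38 per the submitters' processing notes; the aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here. Columns were tied to samples by the number that stands both in the column header and in the sample's title, and groups were taken from the titles.

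The table held 24475 gene identifiers. A symbol was found for 24375 of them in a RefSeq gene table of assembly GRCm38.p6 and for 7 more in GENCODE M21; the other 93 stayed without a name and held 0.271% of the counts of the CD138-sorted library and 15.0% of those of the Blimp1-sorted library. They were kept in totals and calls. Coordinates are from the same RefSeq table. Immunoglobulin genes were not analysed here, so planned shares of antibody genes, heavy chain classes, light chains and variable segments were not computed. Totals and shares of counts cover the analysed genes only.

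Totals were 3240248 counts for the CD138-sorted library and 3812827 for the Blimp1-sorted library. Counts were scaled by TMM in edgeR 4.0.16 (R 4.3.3), with factors of 1.93 and 0.519, to CPM. This scaling moved every ratio of Blimp1-sorted over CD138-sorted by 1.89 on the log2 scale (3.71-fold) relative to total counts; the median log2 ratio of measured genes on it was -2.07. A gene was measured with at least 1 TMM-scaled CPM in either library and at least 10 counts over both. Each fold was given the exact Clopper-Pearson 95% interval for the ratio of 2 counts, computed in scipy 1.17.1 with Python 3.11.15. Reads amplified by PCR without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A gene was called with a fold of at least 4, an interval beyond 2-fold and the filter above; these calls are a rule of size and not a test. A gene with 0 counts in a library passed the fold threshold by this rule, and its interval decided the call; the same held for list members. A fold against 0 counts was computed against a floor of 3 counts per library, which is 0.481 TMM-scaled CPM in the CD138-sorted library and 1.51 in the Blimp1-sorted library. Such a fold is a value against the floor and not the lower end of its interval. For Kif11 it was 62.6-fold, with a lower end of 50.8. Log2 ratios of lists used a prior count of 2, and a list member was called higher at 2-fold or more with an interval that left out 1. With 1 library per group, no test between groups, no p-value and no left-out replicate was possible.

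Gene lists and cell type markers were written before the data were examined. The median log2 ratio of each list with at least 3 measured members was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and a list stood apart below percentile 2.5 or above percentile 97.5. This describes the 2 libraries and is not a test of conditions. Genes named in the text followed a rule of the same date: Sdc1, Prdm1 and Il33; the 12 largest folds in each direction among the calls, leaving out clone-like names; the 10 genes with most counts outside mitochondrial genes; and for each list the 3 most abundant members and the 3 with the largest ratios. Mitochondrial RNA entered through its list. Genes named outside this rule are said to be so. Not every gene that the rule takes is reported here.

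Alternatives set before the data were examined were scaling by total counts, by DESeq2 1.42.0 size factors and by the upper quartile; no filter beyond 1 count; at least 10 TMM-scaled CPM; the fold alone; folds of 2 and 8; thinning of the deeper library to the smaller total; and a prior count of 0.5. Added after seeing the data were TMM factors from genes with at least 50 counts over both libraries, a filter of at least 100 counts over both, and leaving out ribosomal RNA-like genes (mt-Rnr1, mt-Rnr2, Lars2 and the most counted unnamed identifier, which was put among them for its size alone, as an assumption) with the listed exocrine pancreas genes, under TMM and under total counts, and setting counts of 0 to the floor before the fold threshold.

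The fold rule was tested on simulated Poisson counts for the comparison of the Blimp1-sorted with the CD138-sorted library, over 16352 measured genes, with the mean profile of the real libraries and their totals. It called 3.03% of 66 genes changed 3-fold, and 100% of 67 genes changed 6-fold and of 67 genes changed 12-fold, all in the right direction. Of 16152 unchanged genes it called 0.0371%. The intervals held the true fold for 96.5% of the changed genes, and 3 of 60 random lists stood apart. These simulations hold counting error alone. Figures were drawn with matplotlib 3.10.9.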

Results

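The data were RNA-seq read counts from 2 libraries of plasma cells sorted from mouse bone marrow, 1 library per group. Plasma cells are the antibody-secreting end stage of the B cell lineage. In the first library the cells were sorted as positive for CD138, a surface proteoglycan encoded by Sdc1, from mice of the genotype Il33hu/hu. In the second they were sorted by Blimp1, the transcription factor encoded by Prdm1, from mice that carry an mCherry reporter for it. All mice were 10 to 12 weeks old, on a background of 75% C57BL/6NTac and 25% 129S6SvEvTac. The series studies IgE plasma cells after exposure to house dust mite, and the labels of these 2 libraries name no allergen treatment. Gene counts summed to 3240248 in the CD138-sorted library and 3812827 in the Blimp1-sorted library. At least 1 count was found for 22421 genes in the CD138-sorted library and for 10804 in the Blimp1-sorted library, or 10520 after the latter was thinned to the smaller total. With 1 library per group no difference below has a replicate check. Sort, genotype and sequencing run differ together, and so do the sex-linked transcripts given below. Each comparison is therefore between 2 libraries and not between conditions. Folds are on a TMM scale, and the 95% intervals in parentheses cover counting error only.

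The transcripts named by the sorts had more counts in the Blimp1-sorted library. Sdc1 (Entrez gene 20969; GRCm38 chromosome 12, 8771396 to 8793716) had 198 counts in the CD138-sorted library and 1209 in the Blimp1-sorted library, a 19.2-fold difference (16.5 to 22.5). Prdm1 (Entrez gene 12142; chromosome 10, 44437174 to 44528558) had 22 and 165 counts, a 23.6-fold difference (15.1 to 38.7). Its 22 counts lay close to the background of the CD138-sorted library, where receptor genes of nose and tongue had a median of 5 counts, an upper decile of 13 and a maximum of 6442, and markers of other blood and stromal cells had a median of 13. Jchain, which joins the units of polymeric antibodies, was the most abundant named gene of both libraries among the genes analysed, which leave out immunoglobulin genes. It took 8.34% of their counts (Clopper-Pearson interval 8.31 to 8.37) in the CD138-sorted library and 9.49% (9.46 to 9.52) in the Blimp1-sorted library. On the TMM scale Jchain was 4.22-fold higher in the Blimp1-sorted library, and by total counts 1.14-fold higher. Sdc1 and Prdm1 were 5.19-fold and 6.37-fold higher there by total counts. Of 15 measured plasma cell markers, 12 were at least 2-fold higher in the Blimp1-sorted library, among them Xbp1, a driver of the secretory programme, at 10.4-fold (10.1 to 10.8), and Mzb1, a chaperone for antibody assembly, at 3.86-fold (3.69 to 4.04). By total counts Xbp1 was 2.82-fold higher there and Mzb1 about level at 1.04-fold. The median log2 ratio of the plasma cell markers was 2.45, at percentile 96.01 of random lists matched on expression, inside the range that counted as ordinary, and by total counts 6 of the 15 were at least 2-fold higher and 3 at least 2-fold lower. Il33, an alarmin gene and the one named in the genotype of the CD138-sorted library, had 7 counts there and 0 in the Blimp1-sorted library, where a count of 0 allows up to 1.51 TMM-scaled CPM. The CD138-sorted library held 1.12 TMM-scaled CPM, and its 7 counts lay within the receptor gene background given above. No difference in Il33 could therefore be read from these counts. Whether the hu allele gives reads that count towards the mouse gene was not examined.

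Of 16087 measured genes, 2372 were called higher in the Blimp1-sorted library by the 4-fold rule and 3831 in the CD138-sorted library. Of the latter, 2968 were at least 4-fold higher when a count of 0 was set to the floor of 3 counts. The other 863 had 0 counts in the Blimp1-sorted library and were under 4-fold against that floor, so they passed by their interval alone. The Blimp1-sorted library took 38.2% of the calls, or 44.4% with zeros set to the floor, a setting chosen after seeing the data. Across the measured genes the levels of the 2 libraries had a Spearman correlation of 0.41, and these genes are not independent replicates. No count was found in the Blimp1-sorted library for 5907 measured genes, against 41 in the CD138-sorted library. Receptor genes of nose and tongue, which blood cells are not known to use, had a count in 88.2% of 1494 cases in the CD138-sorted library and 4.48% in the Blimp1-sorted library. The split depended on the scaling: 9.58% of the calls were higher in the Blimp1-sorted library by total counts (1144 against 10792 genes), 47.5% by DESeq2 size factors and 61.0% by the upper quartile. It also rested on low counts, as genes with at least 10 TMM-scaled CPM in either library gave 2250 calls higher in the Blimp1-sorted library and 2211 higher in the CD138-sorted library.

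**Figure D1:**
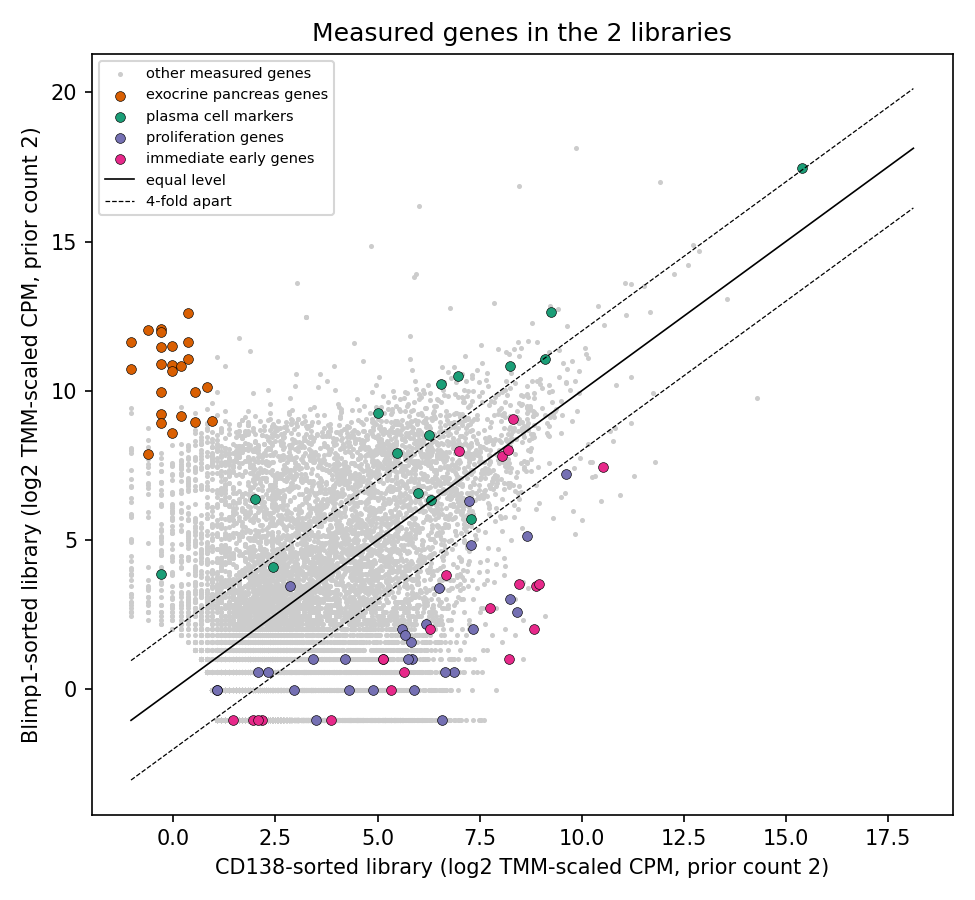
Log2 TMM-scaled CPM (prior count of 2) of each measured gene in the CD138-sorted library (horizontal axis) and the Blimp1-sorted library (vertical axis), with 4 gene groups in colour; the solid line marks equal levels and the dashed lines a 4-fold difference. The exocrine pancreas genes, chosen after their values were seen, sit at the upper left (80 counts in all in the CD138-sorted library and 95815 in the Blimp1-sorted library), and most proliferation and immediate early genes lie below the line of equal levels.

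The 12 largest ratios towards the Blimp1-sorted library all belonged to genes known for secretion by acinar cells of the pancreas. They included the trypsin genes Prss2, Try4 and Try5, the elastase genes Cela2a and Cela3b, the chymotrypsin gene Ctrb1, the lipase gene Pnlip with its cofactor gene Clps, the amylase gene Amy2a5, and Sycn, Reg1 and Rnase1. Prss2 (chromosome 6, 41521776 to 41525079) had 5 counts in the CD138-sorted library and 12329 in the Blimp1-sorted library, a 7767-fold difference (3327 to 23925). Cela2a had 2 and 8579 counts, Ctrb1 had 2 and 8025, and Pnlip had 3 and 5744. Amy2a5 had 0 and 6328 counts, 6644-fold higher in the Blimp1-sorted library against a floor of 3 counts. The trypsin and amylase genes have near-identical copies, and Amy2a2, Amy2a3 and Amy2a4, named after their values were seen, carried the same counts as each other (56 and 11302), so the share of each copy is uncertain.

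Genes of protein folding in the endoplasmic reticulum were higher in the Blimp1-sorted library as a group. Of 27 measured members of the unfolded protein response and folding list, 21 were at least 2-fold higher there and 0 at least 2-fold lower. The chaperone genes Hsp90b1 and Hspa5 were 10.0-fold (9.69 to 10.4) and 6.5-fold (6.17 to 6.84) higher, Herpud1, of the degradation pathway for misfolded proteins, was 9.05-fold higher (8.57 to 9.56), and the disulphide isomerase gene Pdia4 was 44.0-fold higher (38.1 to 51.0). By total counts these 4 genes were 2.71-fold, 1.75-fold, 2.44-fold and 11.9-fold higher, in the same order. The list median was 2.70 on the log2 scale against 1.11 for random lists of matched expression (percentile 99.9), and by total counts it was 0.81, with 13 members at least 2-fold higher and 6 lower. Autophagy and lysosome genes stood apart the same way, with 15 of 20 members at least 2-fold higher and 2 lower (median 2.73, percentile 99.4), and 10 higher and 5 lower by total counts (median 0.90). Among them the protease genes Ctsb and Ctsd were 10.4-fold (9.57 to 11.3) and 99.0-fold (78.1 to 128) higher, and Sqstm1, an adaptor for selective autophagy, was 129-fold higher (95.3 to 180). In the same library 14 of 20 exocrine pancreas genes listed before their values were looked at, 17 of them measured, were at least 4-fold higher. Acinar cells are also rich in folding chaperones. Genes of ER translocation and secretion did not stand apart (percentile 39.3), and their direction turned with the scaling, from 16 of 31 higher and 5 lower on the TMM scale to 7 higher and 14 lower by total counts. N-glycosylation genes did not stand apart either (percentile 79.8), with 13 of 19 higher and 1 lower on the TMM scale and 4 higher and 5 lower by total counts.

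Cell cycle genes were higher in the CD138-sorted library. Of 30 measured proliferation genes, 25 were at least 2-fold higher there and 0 at least 2-fold higher in the Blimp1-sorted library, with a median log2 ratio of -3.93 (percentile 0). Together they took 0.624% of the counts of the CD138-sorted library and 0.0184% of those of the Blimp1-sorted library. Stmn1, a microtubule regulator, was 5.25-fold higher (4.67 to 5.93), and the survivin gene Birc5 was 61.3-fold higher (34.2 to 123). The motor gene Kif11, with 592 counts against 0, was 62.6-fold higher against the floor. By the upper quartile scaling, which favours the Blimp1-sorted library most, 24 of the proliferation genes were still at least 2-fold higher in the CD138-sorted library and 1 was lower.

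Immediate early genes, which cells switch on within minutes of stimulation or tissue dissociation, were also higher in the CD138-sorted library, with 17 of 21 measured members called at least 2-fold higher (16 with zeros set to the floor), 1 lower and a median of -4.13 (-3.20 with zeros set to the floor; percentile 0). Fos had 9106 and 345 counts, an 8.38-fold difference (7.52 to 9.36), Fosb was 44.7-fold higher (29.2 to 72.4) and Zfp36, which destabilises inflammatory mRNAs, was 129-fold higher (62.3 to 320). Of 13 heat shock genes, 6 were at least 2-fold higher in the CD138-sorted library and 5 in the Blimp1-sorted library, 8 and 1 by total counts, and 3 and 5 by the upper quartile. Their median of -1.17 lay at percentile 1.51, but at percentile 11.8 by total counts and 7.88 with genes of at least 10 TMM-scaled CPM. Hspa8 was 8.23-fold higher (7.11 to 9.57) in the CD138-sorted library, while Hspa1b was 9.39-fold higher (8.43 to 10.5) in the Blimp1-sorted library.

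Several markers of earlier B lineage stages had counts almost only in the CD138-sorted library. Of 12 measured B cell precursor markers, 10 were at least 2-fold higher there. Igll1 and Vpreb1, the surrogate light chain genes of precursor B cells, had 1489 and 492 counts in the CD138-sorted library against 1 and 0 in the Blimp1-sorted library. The ratios were 473-fold (84.7 to 18684) and, against the floor, 52.1-fold. Dntt, the polymerase that adds nucleotides at antibody gene joints, had 291 counts against 0, 30.8-fold higher against the floor. Cd93, a marker of precursors that plasma cells also carry, was 4.80-fold higher (4.19 to 5.5) in the Blimp1-sorted library, and 1.29-fold higher by total counts. The median of the precursor markers, -3.13 (-1.80 with zeros set to the floor), lay at percentile 2.495, on the border of the range, and at percentile 3.63 without Cd93, a trim made after its value was seen. It no longer stood apart by total counts (percentile 12.4) or DESeq2 size factors (percentile 3.05). Mature B cell markers did not stand apart (percentile 8.71): 10 of 15 were called at least 2-fold higher in the CD138-sorted library, as were 7591 of all 16087 measured genes. The median of these markers, -1.69, lay above that of all measured genes, -2.07, and below that of random lists of matched expression, -0.55. Among the 10 was Cd72 at 198 counts against 0, whereas Cd79a and Cd79b, the signalling chains of the B cell receptor, were 3.73-fold (3.52 to 3.96) and 3.84-fold (3.59 to 4.11) higher in the Blimp1-sorted library and level by total counts.

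**Figure D2:**
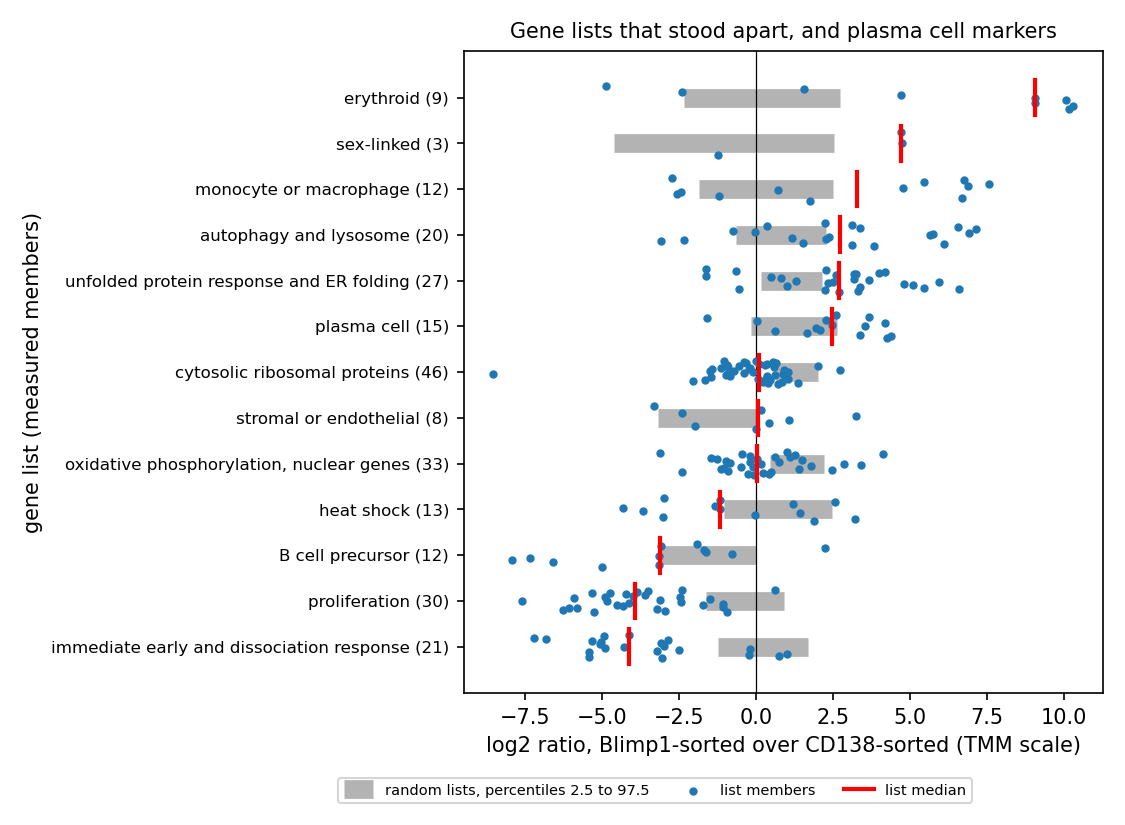
Log2 ratio (Blimp1-sorted over CD138-sorted, TMM scale) of each measured member of the 12 lists that stood apart and of the plasma cell markers; red bars are list medians and grey bars the central 95% of 10000 random lists matched on expression. The medians of proliferation (-3.93) and immediate early genes (-4.13) lie to the left of their grey bars, and those of folding (2.70) and lysosome genes (2.73) to the right; by total counts the medians of ribosomal proteins, oxidative phosphorylation and stromal markers turn below 0.

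Single genes of homing and survival differed in both directions, and the tallies of these lists depended on the scaling. Of 19 homing and adhesion genes, 9 were at least 2-fold higher in the CD138-sorted library and 6 in the Blimp1-sorted library (percentile 29.6), against 13 and 3 by total counts and 6 and 8 by the upper quartile. Klf2 and its target S1pr1, which direct exit of lymphocytes into blood, had 3445 and 185 counts in the CD138-sorted library against 10 and 0. The ratios were 109-fold (59.4 to 228) and, against the floor, 19.6-fold. Itgb7 and Selplg, an integrin chain and a selectin ligand, were 40.5-fold (33.2 to 49.9) and 21.1-fold (18.2 to 24.5) higher in the Blimp1-sorted library. Of 16 survival genes, 8 were at least 2-fold higher in the Blimp1-sorted library and 4 in the CD138-sorted library (percentile 78.7), which turned to 4 and 8 by total counts. Bcl2, which blocks apoptosis, was 7.63-fold higher (6.89 to 8.47) and Cd28, a costimulatory receptor of long-lived plasma cells, was 5.53-fold higher (4.75 to 6.44) in the Blimp1-sorted library, whereas the pro-apoptotic gene Bid was 22-fold higher (7.43 to 108) in the CD138-sorted library. By total counts Bcl2 and Cd28 were 2.06-fold and 1.49-fold higher in the Blimp1-sorted library, and Bid 81.6-fold higher in the CD138-sorted library. Of 10 genes for presentation on MHC class II, 5 were at least 2-fold higher in the Blimp1-sorted library, among them Cd74 at 12.2-fold (11.8 to 12.7) and H2-Ab1 at 18.3-fold (16.3 to 20.6). Another 3 were called at least 2-fold higher in the CD138-sorted library (2 with zeros set to the floor), among them H2-DMa with 724 counts against 2, and by total counts the tally was 4 and 5.

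Markers of other marrow cells differed between the libraries as well, beside each gene group above. Of 9 measured erythroid markers, 7 were at least 2-fold higher in the Blimp1-sorted library (median 9.06, percentile 100), led by the haemoglobin gene Hba-a1 with 16 counts in the CD138-sorted library and 6879 in the Blimp1-sorted library, a 1354-fold difference (833 to 2371). The 7 also included Hba-a2, Hbb-bt, Hbb-b1 and Hbb-b2, named after their values were seen, related globin copies that are not independent markers. Hbb-b2 and Hbb-bt may share reads, as both had 0 counts in the CD138-sorted library and 514 in the Blimp1-sorted library. Of 12 monocyte or macrophage markers, 7 were higher there and 4 in the CD138-sorted library (3 with zeros set to the floor), or 6 and 5 by total counts (median 3.26, percentile 99.5, and 93.0 with no filter on low counts). The complement gene C1qb was 169-fold (81.1 to 423) and the growth factor receptor gene Csf1r 114-fold (78.8 to 171) higher in the Blimp1-sorted library. Stromal or endothelial markers also stood apart (percentile 97.7, and 95.03 with no filter), though of 8 only Col3a1 was at least 2-fold higher in the Blimp1-sorted library, while Lepr and Dcn were at least 2-fold higher in the CD138-sorted library, and by the upper quartile 2 were higher in each. Of 15 neutrophil markers, 7 were at least 2-fold higher in the CD138-sorted library and 1, the lactoferrin gene Ltf, in the Blimp1-sorted library (percentile 3.39), against 13 and 1 by total counts and 4 and 6 by the upper quartile. The 3 sex-linked genes measured differed between the libraries: Xist, transcribed from the inactive X chromosome, had 935 counts in the CD138-sorted library and 125 in the Blimp1-sorted library, and the Y-linked genes Ddx3y and Uty had 1 and 0 against 33 and 24. Xist was 2.37-fold higher in the CD138-sorted library on the TMM scale, 8.80-fold by total counts and 1.29-fold by the upper quartile. The Blimp1-sorted library held counts of both Xist and the Y-linked genes.

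Ribosomal protein genes and nuclear genes of oxidative phosphorylation were lower in the Blimp1-sorted library relative to genes of like expression. The 46 ribosomal protein genes took 3.48% of the counts of the CD138-sorted library and 1.03% of those of the Blimp1-sorted library. Their median log2 ratio was 0.09 on the TMM scale, -1.80 by total counts and 0.96 by the upper quartile, so its sign followed the scaling, while random lists of matched expression had a median of 1.33 on the TMM scale (percentile 0). The 33 oxidative phosphorylation genes had a median of 0.03 on the TMM scale against 1.33 for random lists (percentile 0.12), -1.85 by total counts and 0.91 by the upper quartile. Members of each list diverged. With the proteasome genes, their log2 ratios had an SD of 1.80 around the median of each complex. Rps3 was 6.64-fold higher (6.20 to 7.10) in the Blimp1-sorted library. Rpl30 had 1135 counts in the CD138-sorted library and 0 in the Blimp1-sorted library, 120-fold higher in the former against the floor. Atp5b was 17.5-fold higher (15.5 to 19.8) in the Blimp1-sorted library and Atp5l 8.86-fold higher (7.12 to 11.2) in the CD138-sorted library.

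Single genes took large shares of the counts. In the Blimp1-sorted library 14.9% of counts fell on 1 gene identifier with no name in the reference tables (0.18% in the CD138-sorted library), 6.86% on mt-Rnr2, a mitochondrial ribosomal RNA, 6.22% on Lars2 and 3.91% on Tceanc2. In the CD138-sorted library 3.84% fell on Mrgpra6 and 2.32% on Slpi, a secreted protease inhibitor. Mrgpra6 was 23-fold higher (21.9 to 24.1) in the CD138-sorted library, Tceanc2 was 1176-fold higher (1066 to 1301) in the Blimp1-sorted library, and Slpi was 1.39-fold higher (1.36 to 1.41) in the CD138-sorted library on the TMM scale and higher in the Blimp1-sorted library by the upper quartile. Of the 42 lists with measured members, 6 stood apart towards the Blimp1-sorted library and 6 towards the CD138-sorted library, against 2.1 expected among random lists. This tally only describes the lists, as some share members such as Cd28 and Cd93. The median of the 3 sex-linked genes also mixes Xist with Y-linked genes that go the other way.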

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

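Count calls followed the scaling and the filter on low counts. Genes called higher in the Blimp1-sorted library numbered 1144 by total counts and 1350 by total counts without exocrine pancreas genes and those treated as ribosomal RNA-like (1 of them, unnamed, for its size alone), against 2372 on the TMM scale. Those higher in the CD138-sorted library numbered 10792 and 9448 in these settings, 2005 by the upper quartile, 2211 with at least 10 TMM-scaled CPM, 1726 with at least 100 counts over both libraries, 8739 by the fold alone and 7591 at a fold of 2, against 3831. The other 19 counts stayed within 1.5 times, among them 2372 and 2968 with zeros set to the floor. The share of calls higher in the Blimp1-sorted library was 38.2% on the TMM scale, 9.58% and 12.5% by total counts with and without those genes, 47.5% by DESeq2 size factors, 61.0% by the upper quartile and 26.6% with TMM factors from genes with at least 50 counts. Relative to the TMM scale, log2 ratios moved by -1.89 by total counts, 0.34 by DESeq2 size factors, 0.88 by the upper quartile and -0.48 by the 50-count factors, which is how these counts shift; a stricter filter tests fewer genes. The settings with 50 counts, with 100 counts, with zeros at the floor and without ribosomal RNA-like and exocrine genes were chosen after seeing the data.

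Of 12 lists that stood apart, 8 did so under each setting run: proliferation and immediate early genes (percentile 0 throughout), ribosomal proteins (0 to 0.02), oxidative phosphorylation (0.07 to 0.15), folding (99.8 to 99.97), lysosome (98.7 to 99.6), erythroid (99.94 to 100) and sex-linked genes (99.78 to 99.98). Of these 8, the erythroid list holds globin copies that may share reads, and the sex-linked list has only 3 measured genes, Xist and Y-linked genes of opposite direction. For the other lists of the 12 the cause was not tested. Heat shock genes lay at percentile 11.8 by total counts, 8.63 by total counts without those genes, 7.88 with at least 10 TMM-scaled CPM, 2.63 after thinning and 2.85 with the 50-count factors. B cell precursor markers lay at 12.4 and 11.7 in these total-count settings, 3.05 by DESeq2 size factors, 3.63 with the 50-count factors and 6.84 with at least 100 counts. With no filter, monocyte or macrophage markers lay at 93.0 and stromal markers at 95.03. Lists that newly stood apart were MHC class II at 99.2 with at least 10 TMM-scaled CPM and 99.1 with at least 100 counts, NF-kB targets at 1.43 and 0.30 and neutrophil markers at 1.93 and 2.11 in the same settings, homing genes at 0.42 with at least 100 counts, and interferon genes at 97.54 by total counts and 97.8 by the upper quartile. Of the named genes, Slpi alone changed sign, at a log2 ratio of 0.41 by the upper quartile. Settings that leave out immunoglobulin genes or concern antibody gene shares were not run, as those genes were not analysed here. No paired analysis was possible because each group holds 1 library. Depth also limits single genes: 3 counts stand for 1.51 TMM-scaled CPM in the Blimp1-sorted library and 0.481 in the CD138-sorted library.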

Other observations

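The tests of depth, of counting error and of lost transcripts below were chosen only after the results they bear on had been seen, as was the requirement for more measured islet genes; the other tests were written down first.

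Signalling genes that the report does not cover differed in both directions between the 2 libraries. Of 18 measured genes of Fc receptors and B cell receptor signalling, 7 were at least 2-fold higher in each library on the TMM scale (percentile 24.4), and 11 in the CD138-sorted and 5 in the Blimp1-sorted library by total counts, and 6 and 9 by the upper quartile. Fcgr2b, the inhibitory IgG receptor, had 576 counts in the CD138-sorted library and 3 in the Blimp1-sorted library, a 61.0-fold difference (20.8 to 296), whereas the kinase gene Btk and the phospholipase gene Plcg2 were 60.4-fold (33.9 to 119) and 19.4-fold (16.4 to 23.2) higher in the Blimp1-sorted library. Of 20 cytokine receptor and type 2 signalling genes, 9 were at least 2-fold higher in the CD138-sorted library and 7 in the Blimp1-sorted library (percentile 45.6), against 13 and 4 by total counts and 6 and 7 by the upper quartile. The neighbouring genes Stat5a and Stat5b went opposite ways, with 211 and 183 counts in the CD138-sorted library against 1 and 705 in the Blimp1-sorted library. Il2rb had 1 count against 481, and Il10ra 163 against 0. Of 14 NF-kB targets, 6 were at least 2-fold higher in the CD138-sorted library and 2 in the Blimp1-sorted library (percentile 64.9), against 10 and 1 by total counts and 3 and 3 by the upper quartile. Their percentile ran from 0.30 to 77.3 over the settings run, and with stricter filters on low counts the list stood apart towards the CD138-sorted library. The chemokine gene Ccl3 had 1222 counts against 0, 129-fold higher in the CD138-sorted library against the floor of 3 counts. The inhibitor gene Nfkbia was 9.32-fold higher (8.67 to 10.0) in the Blimp1-sorted library.

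Of 16 amino acid genes, 5 were at least 2-fold higher in each library on the TMM scale (percentile 42.6), 10 in the CD138-sorted and 3 in the Blimp1-sorted library by total counts, and 4 and 7 by the upper quartile. The leucine transporter gene Slc7a5 was 161-fold higher (112 to 242) in the Blimp1-sorted library, and of the serine synthesis genes Phgdh was 17.6-fold higher (15.3 to 20.2) there while Psat1 had 309 counts in the CD138-sorted library and 1 in the Blimp1-sorted library. Neither eosinophil nor basophil or mast cell markers stood apart (percentiles 77.7 and 83.2). Of 6 eosinophil markers, 3 were at least 2-fold higher in the Blimp1-sorted library, with Prg2 at 8.29-fold (7.88 to 8.73), and 1, Il5ra, in the CD138-sorted library, against 2 and 3 by total counts. Of 8 basophil or mast cell markers, 3 were at least 2-fold higher in the Blimp1-sorted library, with Prss34 at 155-fold (95 to 273), and 2, Ms4a2 and Gata2, in the CD138-sorted library, against 2 and 5 by total counts and 3 and 0 by the upper quartile.

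Pancreatic enzyme genes reached high counts in the Blimp1-sorted library: 24 exocrine genes picked from the largest ratios, 1 of them also in a marker list, held 2.51% of its counts, led by Prss2 with 12329, and the amylase genes Amy2a2, Amy2a3 and Amy2a4, outside that pick and named after their values were seen, had 56 counts each in the CD138-sorted library and 11302 each in the Blimp1-sorted library. Of 20 exocrine genes listed before their values were looked at, 17 were measured, and 14 of these (82.4%) were at least 4-fold higher in the Blimp1-sorted library. That lay at percentile 100 of matched random lists, whose highest count was 8, which argues against uneven amplification of single molecules as the whole cause. The filter favours genes with counts in that library, as the unmeasured Cuzd1, Ptf1a and Dpep1 had 0 there. Trypsin genes such as Prss1 and Try10 may share reads with the first pick, so not all 14 are independent. These 5 genes were named after their values were seen. The same 82.4% is what RNA or reads from pancreas would give, and a candidate source is acinar tissue or a pancreas library, in the sample, the preparation or the sequencing run, although the cells were sorted by Blimp1 and the labels name marrow. A secretory programme of plasma cells shared with acinar cells stays open: 1 of only 4 measured islet genes was at least 4-fold higher, the insulin gene Ins2 (named after its values were seen) with 6 and 144 counts, too few to decide. A low number of islet genes could not decide it in any case, as RNA from exocrine tissue alone would give the same. Lists of other tissues gave 4 of 10 liver genes, 3 of 6 lung, 0 of 6 kidney, 1 of 3 intestine, 3 of 4 skeletal muscle, 1 of 8 brain and 1 of 2 salivary gland genes at least 4-fold higher in the Blimp1-sorted library, as were 2372 of all 16087 measured genes. In the CD138-sorted library 1 gene each of the liver, lung, kidney, intestine, brain and salivary gland lists was called higher, that of brain not with zeros set to the floor. These lists are small, and the filter favours such tallies here too, as 4 of 8 skeletal muscle and 6 of 8 lung genes were measured. All genes of these 2 lists held 183 and 652 counts in the Blimp1-sorted library, against 1481 for the 20 exocrine genes listed unseen. The lung and skeletal muscle tallies therefore cannot decide whether such a share is specific to pancreas.

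Low counts covered nearly all genes of the CD138-sorted library. A greater total is argued against, since this library had the smaller total and, at equal totals, 11901 more genes with a count. Equal totals do not give most genes equal depth, as the 10 most counted genes held 47.6% of the Blimp1-sorted counts and 21.5% of the CD138-sorted counts. The test therefore cannot exclude greater depth over the remaining genes as part of the cause. A wider mix of cell types alone is argued against too: of 1494 receptor genes of nose and tongue, which blood cells are not known to use, 88.2% (86.4 to 89.7) had a count there, with a median of 5, against 4.48% (3.49 to 5.66) in the Blimp1-sorted library. That share is what reads from genomic DNA or another source that covers silent genes would give, so such reads may underlie part of the low counts, although the protocol has a DNase step; a change in the sorted cells themselves was not tested. The 65 markers of other blood and stromal cells had a median of 13 counts there and 0 in the Blimp1-sorted library.

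Ratios scattered widely within complexes whose genes are usually expressed together. Over 104 ribosomal protein, proteasome and oxidative phosphorylation genes, the SD of log2 ratios around the median of each complex was 1.80. Counting error of independent reads is argued against as the whole cause, since the counting intervals of 94 of the 104 genes left out the median of their complex, against at most 12 in 1000 simulated draws, which does not tell technical from biological scatter. Overlap with another annotated gene cannot be told apart from chance placement at these numbers: 10 of 18 genes over 4-fold from the median overlapped another gene and 36 of the 86 others did, a difference of 13.7 percentage points. Transcripts lost or over-amplified from few starting molecules remain a candidate explanation resting on 1 gene, Rpl30, with 0 counts in the Blimp1-sorted library where 383 would match its complex, and real differences between the sorted cells stay open as untested.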
